A study of Parascaris univalens with 7 samples.

How the data were processed

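Adult worms of a North American wild-type strain of Parascaris univalens were taken from horse intestine and dissected, and the tissues were frozen; embryos were kept cold, per the labels' protocols. RNA was extracted with Trizol, and libraries were made from rRNA-depleted total RNA with a TotalScript kit, per the labels' protocols. There were 7 libraries: 1 each of testis, ovary, embryo, intestine and carcass, and 2 from mixed samples, a spliced leader PCR library and a TeloPrime PCR library of 5′ ends. The depletion kit was made for human, mouse and rat rRNA, per the labels' protocols, which bears on how much ribosomal sequence the values hold.

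The deposited table lists 40487 transcripts of 15027 genes with scaffold, start, end, strand, exon number, length, annotation text, marks for the 5′ libraries and for eliminated DNA, and 1 expression value per tissue. The authors' expression values are RPKM to 1 decimal; the unit was taken from the values, which rise in steps of whole reads divided by transcript length. TopHat2 and Cufflinks are named in the submitters' processing notes, with no version or role. The genome build, the counting of reads that match several loci and the way genes were marked as eliminated are not given in the sources used here, nor is the meaning of the scaffold names PgR, PgB and PgE or of an X at their end. Each transcript of a gene has its own value, and 7964 genes have more than 1 transcript. Strand is missing for 1041 genes, all with a single exon, and the reads of such a gene may be those of an overlapping one. Of all genes, 443 lie wholly inside a gene on the opposite strand, 222 of them inside one with the same annotation, and whether the reads kept their strand is not stated in the sources used here. Among the 179 genes that the naming rule picked these numbers are 20 and 11. Those of the 20 named in the text are PgB03_g005, PgB03_g120, PgR003_g017, PgR012_g130, PgR022X_g125, PgR045_g017, PgR047_g059, PgR059_g044, PgR126X_g020 and PgR166_g004, inside genes with the same annotation, and PgR004_g225, PgR007_g161, PgR007_g177, PgR116_g015 and PgR139_g003, inside others; reads of 1 locus may be counted at both genes. In 1 case near-equal values were found at 4 genes with the same annotation and length (PgB32_g005, PgR060_g044, PgR089_g029 and PgR089_g030). Each had between 1406 and 1441 RPKM in testis and between 10886 and 11052 in intestine. Reads that match all copies may have been counted at each or divided among them, and the values do not tell which. Values of genes in families with near-identical members, such as the major sperm proteins, are uncertain for that reason. No columns of other samples were found (0), and the mixed libraries have no expression values in the table.

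A gene was represented by the transcript with the highest mean value over the tissues. Differences were taken on log2(RPKM + 1), and a gene was called higher in a tissue at a difference of 2 or more (4-fold) with at least 5 RPKM in the higher tissue. Germline against soma used the lower of testis and ovary and the higher of intestine and carcass, and the reverse. A gene was enriched in a tissue when this rule held against each of the other 4 tissues. With 1 library per tissue no p-value between tissues was computed. The similarity of tissues is a Pearson and Spearman correlation across genes. The 26 gene lists were made by searching fixed words in the annotation text, and each list's median difference was placed among 10000 random lists of the same size, matched on mean expression in 20 bins; a median in the lowest or highest 2.5% was called outside their range. Bootstrap intervals of list medians used 2000 resamples of the members. Annotations are names carried over by similarity, and 4415 genes were annotated as hypothetical or uncharacterized. Some list members do not do what the list's name says, such as desaturases and elongation factors found by the word delta, paxillin found by pax (PgR080_g029; 188 RPKM in testis) and mitochondrial ribosomal proteins among the ribosomal ones. Eliminated and retained genes, and genes with and without 5′ marks, were compared by two-sided Fisher's exact tests across genes, which are not replicates, with Benjamini-Hochberg adjustment over the 5 tissues, the 26 lists or the 10 tests of 5′ marks. A gene counted as eliminated by the mark of its representing transcript; 3 genes had transcripts with different marks.

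The genes named in the text are taken by a fixed rule. For each comparison they come from the 12 with the largest difference in each direction among genes with at least 20 RPKM in the higher tissue and an informative annotation, 1 per annotation text; for enrichment from the 5 highest per tissue, and for each list from the 4 members with the highest mean. Groups, lists, thresholds, tests and most alternatives were fixed before the data were examined. The comparison of 5′ marks, the accounts of eliminated families, of scaffold names and of shared signal between tissues, and the genes named in them, were chosen afterwards.

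Depth was estimated from transcripts of at most 350 nt with under 15 reads, as the number of reads that puts most of their low values on whole reads. Within 0.2 of a whole read lay 15 of 16 usable values in testis, 11 of 11 in ovary, 255 of 258 in embryo, 58 of 63 in intestine and 37 of 40 in carcass. When values were shuffled between transcripts, 0 of 100 shuffles scored as high in testis, embryo, intestine and carcass, and 1 of 100 in ovary. Counting intervals of RPKM values are exact 95% Poisson intervals from this depth, and intervals of shares are exact (Clopper-Pearson) 95% binomial intervals. The Poisson intervals cover counting error only, and PCR copies are not independent molecules. The binomial intervals are across genes, which are not replicates. The embryo had the lowest depth and so the widest intervals.

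The calling rules were tested on simulated data made from the real genes, with 200 changed genes. Among the 14827 unchanged genes, 0 were called in each comparison, but the simulation holds counting noise only, against which a 4-fold rule makes hardly any call, and variation between animals or libraries is not in it. Of genes changed 2-fold, 0% were called. At 4-fold, the threshold itself, 16% were called for testis against ovary, 32% for intestine against carcass, 14% for embryo against ovary, 6% for germline against soma and 0% for testis enrichment, and at 8-fold and 16-fold 100% were called in each. Of 100 unshifted random lists of 50 genes in testis against ovary, 9% lay outside the range of random lists, where 5% would by chance, and of lists shifted by 1 log2 unit 100% did.

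The alternatives tried were other pseudocounts, filters, fold thresholds, a tau index of tissue specificity, median-of-ratios, upper-quartile and TPM scaling, values summed per gene, and removal of the 20 highest genes of each tissue. After that removal each tissue was rescaled to the same sum of RPKM, and the shifts include this rescaling. TPM divided the values by factors from 0.441 in intestine to 0.654 in embryo. The pseudocount and cutoffs were kept, so TPM calls were made at a looser cutoff. Added after the data were seen were rescaling of each library without the reads of the rDNA-related genes, the authors' best expressed or largest transcript, subtraction of the signal shared between tissues, 1 gene per annotation text, and removal of genes that lie inside a gene on the opposite strand. The rescaling dropped no gene. For the tests of elimination, 1 gene per annotation text was kept among eliminated and 1 among retained genes, and for scaffold names 1 in all. Genome sequence was not used here. Not every gene that the naming rule picked is reported here. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.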

Results

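RNA was sequenced from 5 tissues of the horse roundworm Parascaris univalens, a nematode whose germline cells keep the whole genome while the cells that become somatic in the early embryo discard part of it, a process called programmed DNA elimination. The tissues were testis, ovary, embryo, intestine and carcass, the body that remains after dissection, with 1 library each. The labels call testis and ovary the male and female germline, and they call embryo, intestine and carcass all male somatic. Another 2 libraries, from mixed samples, were made to find the 5′ ends of transcripts and entered only as marks on each transcript. The gene table held 15027 genes on 884 scaffolds, each with an RPKM value (a read count scaled by transcript length and library depth) in every tissue and a mark that said whether the gene lies in eliminated DNA. With 1 library per tissue there was no replicate error to set a difference against. Differences between tissues are therefore given as values of these libraries, without p-values, and intervals of RPKM values cover counting error only. Intervals of list medians, shares and odds ratios are across genes. Differences on the log2(RPKM + 1) scale understate the folds of low genes.

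The depth recovered from the spacing of low values was about 31350000 reads for testis, 31800000 for ovary, 11900000 for embryo, 18600000 for intestine and 27450000 for carcass. A transcript of the median length, 1325 nt, with 3 reads would have an RPKM of 0.0722 in testis, 0.0712 in ovary, 0.190 in embryo, 0.122 in intestine and 0.0825 in carcass. At least 1 RPKM was listed for 11091 genes in testis, 10451 in ovary, 11582 in embryo, 9419 in intestine and 9703 in carcass. The 20 highest genes held 52.9% of the summed values in embryo, against 26.1% in testis, 24.0% in ovary, 37.8% in intestine and 36.5% in carcass. In the embryo, 25 genes annotated as regulator of rDNA transcription, TAR1 or R2 retrotransposable element took 19.6% of reads, against 0.618% in testis, 1.10% in ovary, 3.37% in intestine and 3.03% in carcass. These names belong to sequence within or beside ribosomal DNA. Across genes, which are not independent replicates, ovary and embryo were the most similar of the 10 pairs of tissues (Pearson r = 0.794, Spearman rho = 0.793), followed by intestine and carcass (r = 0.719, rho = 0.732). Testis and carcass were the least similar (r = 0.376, rho = 0.407).

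The comparison of testis with ovary asked which genes separate the male from the female germline. The testis was led by the genes of the crawling nematode sperm. Major sperm protein isoform beta (PgE404_g001), a cytoskeletal protein that moves the sperm, stood at 6856 RPKM in testis (counting interval 6834 to 6877) and 1.2 in ovary (0.930 to 1.52), a log2 difference of 11.61. This gene lies on scaffold PgE404 between positions 1462 and 4458 on the minus strand, has 3 exons, and is marked as eliminated. An eliminated gene annotated as tyrosine-protein kinase Fer (PgE050_g003) stood at 6163 RPKM against 1.4, MSP-domain protein 1 (PgR011_g012) at 4529 against 1.2, and MSP-domain protein 4 (PgR345_g001) at 2780 against 3.4. MFP1-beta (PgR166_g004), MFP2b (PgR047_g059) and MFP2c (PgR019_g016), members of the families that regulate assembly of major sperm protein filaments in Ascaris sperm, stood at 2176, 2088 and 762 RPKM in testis and at 1.4, 2.7 and 0.1 in ovary; the first 2 lie inside genes of the same annotation on the opposite strand, so their reads may not be separate. Genes annotated as an ATP-binding subunit of the clp protease (PgR052_g015), KCTD16 (PgR002_g252), receptor expression-enhancing protein 6 (PgR026_g047) and the collagen alpha-2(IV) chain (PgR116_g015) completed this end of the range with 2410, 1727, 920.4 and 718 RPKM in testis and at most 0.4 in ovary. Alanine aminotransferase 2 (PgR104_g007) was at 823 RPKM in testis and 0.3 in ovary, and also at 899 in intestine.

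At the other end of this comparison, chondroitin proteoglycan 3 (PgR176_g006), of a family of eggshell proteoglycans in nematodes, stood at 20766 RPKM in ovary (20721 to 20812) and 42.6 in testis (40.6 to 44.7), a log2 difference of −8.90. Transthyretin-like protein 16 (PgR080_g022) was listed at 1442 RPKM in ovary and 0.2 in testis, a c-type lectin (PgR022X_g125) at 1532 and 0.4, and ankyrin repeat domain-containing protein 12 (PgB05_g043) at 7715 and 7.8. The immunosuppressive ovarian message protein (PgR020_g100) was at 4105 RPKM in ovary and 4.4 in testis, and an ovarian abundant message protein (PgR099_g019) at 424 and 0.1. A trypsin family gene (PgR010_g099), mannose-6-phosphate isomerase (PgR006_g084) and C-type mannose receptor 2 (PgR025_g089) stood at 2435, 1098 and 3850 RPKM in ovary and at 3.1, 1.2 and 8.9 in testis. Venom allergen 3 (PgR059_g015) and a zonadhesin (PgR006_g052) were listed at 0 in testis, with 444 and 319 RPKM in ovary. Thioredoxin domain-containing protein 12 (PgR011_g175), at 339 RPKM in ovary and 0.2 in testis, was also at 297 in carcass.

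In all, 1740 genes were higher in testis and 2391 in ovary by at least 4-fold with at least 5 RPKM in the higher tissue. The direction of the bulk of genes depended on scaling, and the balance of the calls on threshold and pseudocount as well. The median log2 difference of genes with at least 1 RPKM in either tissue was −0.89 as deposited. Median-of-ratios scaling shifted it by 1.03, upper-quartile scaling by 0.68, removal of the 20 highest genes of each tissue with rescaling to equal sums by 0.18 and TPM by 0.11. Only median-of-ratios scaling, which pulls the median ratio towards 0 by construction, turned the sign of this median (0.13). With upper-quartile scaling the median was −0.21. Testis-higher genes made up 42.1% of the calls as deposited, 72.0% (2162 against 839) with median-of-ratios and 63.4% (1934 against 1119) with upper-quartile scaling. Calls were 1454 against 892 with an 8-fold threshold, 2108 against 5211 with a 2-fold threshold and 1292 against 1132 with a pseudocount of 5. The gene lists were therefore set against random lists of like expression. Of 75 sperm and major sperm protein genes, 56 were higher in testis, 2 in ovary and 17 in neither. Their median difference of 4.76 (bootstrap interval 4.03 to 6.06) lay above all 10000 random lists, whose median was −0.46. Of 568 protein kinases and PP1-type phosphatases, 208 were higher in testis, 59 in ovary and 301 in neither (median 0.19, percentile 100). PP1 phosphatase PgR011_g026, at 852 RPKM in testis and 16.5 in ovary, was among them. Histones leaned to ovary, with 15 of 34 higher there and 1 in testis (median −1.72, percentile 0.02), among them histone H2B 2 (PgR052_g010) at 12719 against 321 RPKM and histone H4 (PgR012_g130) at 8832 against 314. DNA replication genes were higher in ovary in 15 of 58 cases and in testis in 0 (median −1.51, percentile 0.53). The catalytic subunit of DNA polymerase zeta (PgB01_g083) had 248 RPKM in ovary and 39.3 in testis. Wnt, Notch and Hedgehog-related genes (26 of 131 higher in ovary, 3 in testis, percentile 0.34) and mitochondrial respiration genes (17 of 80 against 1, percentile 1.1) also lay below their random lists, with patched-related protein 9 (PgR055_g005) at 416 RPKM in ovary and 8.8 in testis. Some members of the signalling list were caught by the word delta alone, such as elongation factor 1-beta/1-delta 1 (PgR137_g015, 340 RPKM in ovary and 184 in testis). Neuronal genes (23 of 175 higher in ovary, 8 in testis) had a median of −0.49 at percentile 0, but of 0.00 at percentile 27 with median-of-ratios scaling.

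Germline against soma set the lower of testis and ovary against the higher of intestine and carcass, and the reverse, because the tissues are not replicates of a class. A PP1-gamma catalytic subunit (PgB01_g119), a protein phosphatase, stood at 178 RPKM in testis and 257 in ovary, against 2.8 in intestine (2.32 to 3.37) and 2.3 in carcass (1.93 to 2.72). Phosphoenolpyruvate carboxykinase (PgR044_g051), which makes phosphoenolpyruvate from oxaloacetate, had 738 and 821 RPKM in the germline tissues and 21.9 and 11.2 in the somatic ones. Caprin-1 (PgR008_g011) and the gap junction protein innexin-3 (PgR021_g047) had at least 36.5 RPKM in both germline tissues and at most 0.8 in intestine and carcass. The other 8 of the 12 leading genes are marked as eliminated: the helicase brm (PgE113_g002), 60S ribosomal protein L17 (PgE321_g001), CCR4-NOT subunit 2 (PgE616_g001), filamin-A (PgE285_g001), 40S ribosomal protein S19G (PgE026_g002), lamin-1 (PgE188_g001), SMC3 (PgE027_g003), a subunit of cohesin, and glycogen synthase kinase-3 beta (PgE022_g006). They ranged from 20 RPKM (GSK-3 beta in testis) to 67.6 (L17 in testis) in the germline, and none exceeded 0.8 in intestine or carcass. On the somatic side, a vitellogenin-6 (PgR126X_g020), a yolk protein, stood at 628 RPKM in intestine and 137 in carcass, against 1.1 in testis and 0.2 in ovary, although both somatic tissues are labelled male. Over the 102 genes with at least 100 RPKM in intestine and no more than a hundredth of that in ovary, the carcass value was a median 19.6% of the intestinal one (quartiles 16.4% and 22.8%), and the carcass value of this gene lies in that range, so its call for both tissues may rest on a share of intestinal signal. The antimicrobial peptides ASABF-alpha (PgR019_g012) and ASABF-beta (PgR004_g225) had 81.7 and 28.8 RPKM in intestine and 940.3 and 155 in carcass, with at most 1.7 in the germline. Acetyl-CoA acetyltransferase A (PgR127_g002) had 39.8 RPKM in intestine and 1522 in carcass, medium-chain acyl-CoA dehydrogenase 10 (PgR002_g104) 156 and 197, and a 3-hydroxyacyl-CoA dehydrogenase (PgR093_g004) 49.2 and 36.6, all with at most 9.0 in the germline. Trehalase (PgB14X_g002), which splits the sugar trehalose, stood at 117 and 87.5 RPKM against 5.8 and 2.4.

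This comparison found 505 genes higher in germline and 255 higher in soma, so that 66.5% of the calls were germline-higher as deposited. That share was 36.8% (308 against 528) with median-of-ratios scaling, 37.9% (311 against 509) with upper-quartile scaling and 55.8% (368 against 291) without the 20 highest genes of each tissue and with sums made equal. Small RNA and germ granule genes (9 of 24 higher in germline, 0 in soma, median 1.16) and genes of mitosis and chromosome segregation (20 of 89 against 0; median 1.10) both lay above all random lists. The Argonaute CSR-1 (PgR178_g009) had 75.8 RPKM in testis and 66.7 in ovary, against 2.4 in intestine and 1.1 in carcass. DNA replication genes (4 of 58 against 0; median 0.84) and histones (0 of 34 called; median 0.75) were at percentile 100 as well. Genes of translation factors (6 of 115 against 0), splicing (0 of 105 called), ribosomal proteins (7 of 193 against 0) and chaperones (4 of 84 against 1) also lay above the 99th percentile. Their own medians were small: 0.18, 0.09, −0.19 and 0.01, and those of translation factors, splicing and chaperones were below 0 with median-of-ratios and upper-quartile scaling. The chaperones lay within the range of random lists with median-of-ratios scaling (percentile 95.8). Meiosis genes (3 of 18 higher in germline, 0 in soma; median 0.28) were at percentile 97.2, within the range of random lists, but above it among members with at least 1 RPKM in some tissue (percentile 97.52), with values summed per gene (97.94) and with TPM (98.84), and on its upper bound with median-of-ratios scaling. Below the range of random lists lay innate immunity and host interface (11 of 91 higher in soma, 4 in germline; median −2.05), muscle (2 of 85 against 2; −1.59), nutrient transport and lipid handling (10 of 174 against 7; −0.94), and haem and oxygen handling (2 of 81 against 0; −1.0). So did neurons (1 of 175 against 0; −0.59), anthelmintic drug targets (0 of 70 against 1; −0.59) and cuticle collagens and cuticlins (2 of 211 against 1; −0.26). Yolk proteins had 3 of 4 members higher in soma (median −8.62), but 2 of these, PgR126X_g019 and PgR126X_g020, lie inside the span of the other, PgR126X_g018, on the opposite strand, so that the 3 may hold reads of 1 locus. List medians in this comparison take the lower germline value less the higher somatic one, so a low median can come from 1 tissue alone. The reverse was counted for calls but not taken for list medians. A low median therefore does not show that a list leaned to both somatic tissues. The sperm list also lay below random lists (median −0.93, percentile 0.64), since its genes were low in ovary, and 1 of its 75 members was higher in both germline tissues.

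Intestine and carcass are the adult somatic tissues. The carcass, which holds the cuticle and the body wall muscle, was led by structural genes. Cuticle collagen 10 (PgR003_g087) stood at 611 RPKM in carcass (601 to 621) and 0.2 in intestine (0.040 to 0.563). A putative cuticular collagen (PgR059_g044) was at 11966 and 24.9, and cuticle collagens 19 (PgR046_g017), 12 (PgR031_g047), 13 (PgR045_g017) and 34 (PgR046_g036) between 1143 and 7161 in carcass and between 2.3 and 21.3 in intestine. Troponin I 2 (PgR103X_g011), which regulates muscle contraction, was at 1335 RPKM in carcass and 1.9 in intestine. Glutathione S-transferase 4 (PgR024_g121) had 1979 against 5.0, OV-17 antigen (PgR020_g116) 1571 against 3.8 and lymphocyte antigen 75 (PgR135_g005) 773 against 1.2. A gene annotated cox18 (PgR049_g044) was listed at 478 RPKM in carcass and 0 in intestine, and the hedgehog-related cre-grl-4 (PgR026_g103) at 457 and 0.4. On the intestinal side the differences were smaller. Over the 102 intestine-abundant genes described above, the carcass value was a median 19.6% of the intestinal one. A share of intestinal signal in the carcass would limit these differences, and it was not subtracted. Rab-like protein 3 (PgB03_g120) stood at 30.8 RPKM in intestine (27.1 to 34.9) and 0.8 in carcass (0.404 to 1.55), amiloride-sensitive cation channel 4-A (PgR045_g049) at 123 and 8.0, and the prohormone-processing enzyme neuroendocrine convertase 1 (PgR003_g064) at 46 and 2.7. A cytosolic branched-chain aminotransferase (PgR103X_g019) had 996 RPKM against 100.2, the H protein of the glycine cleavage system (PgR062_g041) 130.1 against 12.7, and the acyltransferase of the branched-chain ketoacid dehydrogenase (PgR009X_g206) 84.8 against 8.3. The regulators forkhead box protein D3 (PgR009X_g179), a doublesex- and mab-3-related factor (PgR033_g082), the caudal-type homeobox gene pal-1 (PgR134_g022) and the Notch ligand delta (PgB05_g075) had 29.8, 31, 30.1 and 30.4 RPKM in intestine and at most 2.4 in carcass.

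Across all genes, 744 were higher in intestine and 1079 in carcass, and the median difference was 0.59. Scaling by median of ratios shifted that median by −0.56, by upper quartile by −0.51, by TPM by 0.34 and by equal sums without the 20 highest genes by 0.25. Intestine-higher genes made up 40.8% of the calls as deposited, 12.7% (222 against 1532) with median of ratios, 14.8% (256 against 1475) with upper quartile, 58.6% (1757 against 1241) with TPM and 53.4% (1168 against 1020) by equal sums without the 20 highest genes. TPM values are larger than RPKM while the cutoffs stayed, so more genes passed them in both directions. A 2-fold threshold gave 2835 genes higher in intestine against 1370 in carcass, and an 8-fold threshold 42 against 766. Cuticle collagens and cuticlins had 49 of 211 members higher in carcass and 1 in intestine, muscle genes 33 of 85 against 4, and innate immunity genes 30 of 91 against 9; all 3 medians (−0.13, −0.72 and −0.21) lay below every random list. Mitochondrial respiration genes were mostly uncalled (75 of 80), with a median of −0.03 where random lists had 0.54, and 0.34 with TPM. Haem and oxygen handling genes, 15 of 81 higher in carcass and 4 in intestine, were at percentile 2.47, and within the range of random lists with a pseudocount of 0.1 (percentile 2.605). Histones (8 of 34 higher in intestine, 0 in carcass; median 1.58), splicing genes (4 of 105 against 0; 0.86) and yolk proteins (3 of 4 against 0; 2.20) lay above the random lists. Of the 260 genes of the digestive peptidase list, 18 were higher in intestine, 29 in carcass and 213 in neither; the list was at percentile 6.74, within the range of random lists, but below it with median-of-ratios (percentile 1.21) and upper-quartile scaling (1.46). That list mixed gut enzymes such as aminopeptidase N (PgR003_g017; 2322 RPKM in intestine, 333 in carcass) with peptidase inhibitors such as chymotrypsin/elastase isoinhibitors (PgR007_g161; 45.5 and 1259).

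Embryo against ovary sets the developing animal beside the tissue that supplies its egg. A fatty acid-binding protein (PgR015_g036) stood at 3766 RPKM in embryo (3722 to 3811) and 9.7 in ovary (8.36 to 11.2), a log2 difference of 8.46, and also at 857 in carcass. A putative chitinase (PgR006_g117) was at 181 RPKM in embryo, 0.3 in ovary and 0 in intestine and carcass. The astacin-type metalloproteinase nas-34 (PgR011_g092) and a glutathione peroxidase (PgR108X_g021) were listed at 102 and 76.5 RPKM in embryo and at 0 in ovary. Regulator of rDNA transcription protein 15 (PgR046_g002), of the rDNA-related genes described above, had 52530 RPKM in embryo and 463 in ovary. The other 7 of the 12 leading embryo genes were abundant in intestine. C-type lectin protein 160 (PgR010_g147) had 1154 RPKM in embryo, 4.6 in ovary and 11305 in intestine, so that the embryo value was 10.2% of the intestinal one. This percentage was 9.62 for aminopeptidase N (PgR003_g017), 9.82 for the proton myo-inositol cotransporter (PgR035X_g046), 10.8 for carbonic anhydrase 5 (PgB03_g005) and for alanine aminotransferase 2 (PgR104_g007), 10.1 for maltase-glucoamylase (PgR007_g177) and 9.65 for the intermediate filament protein ifa-1 (PgR129_g010). Among all 102 genes with at least 100 RPKM in intestine and no more than a hundredth of that in ovary, the embryo value was a median 10.3% of the intestinal value (quartiles 9.80% and 11.6%).

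**Figure D1:**
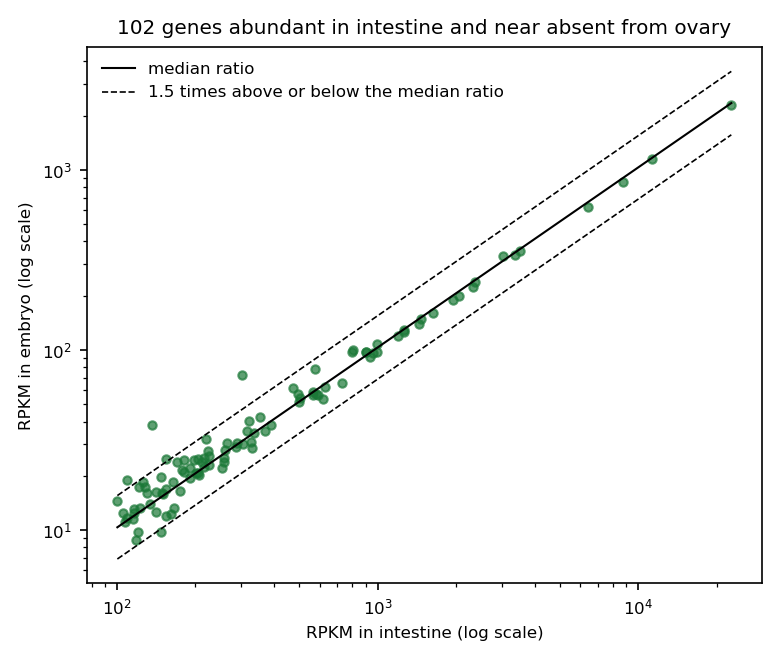
Embryo RPKM against intestine RPKM, both on log10 axes, for the 102 genes with at least 100 RPKM in intestine and at most a hundredth of that in ovary; each point is 1 gene in 1 library per tissue, and the line marks the median share of 10.3%. The points follow the line over the whole range of intestinal values, and the lowest share is 6.64%.

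Genes higher in ovary than in embryo were led by ovary genes already described: the c-type lectin PgR022X_g125 (1532 RPKM against 0.5), transthyretin-like protein 16 (PgR080_g022; 1442 against 1.3), the trypsin family gene PgR010_g099 (2435 against 3.9) and venom allergen 3 (PgR059_g015), listed at 0 in embryo. Chondroitin proteoglycan-2 (PgR008_g092) was at 1441 RPKM in ovary and 3.4 in embryo, a zonadhesin (PgR004_g030) at 731 and 0.7, and RNA-binding protein 39 (PgB02X_g040) at 713 and 1.1. Transthyretin-like proteins 15 (PgR029_g111) and 5 (PgR146_g007) had 335 and 321 RPKM in ovary, and the first was listed at 0 in embryo and the second at 0.4. The chymotrypsin/elastase isoinhibitors of PgR007_g161 stood at 1683 RPKM in ovary and 8.0 in embryo. In all, 801 genes were higher in embryo and 669 in ovary, with a median difference of −0.22. Of the 801 genes, 211 (26.3%) stood at no more than double the 10.3% share of their intestinal value. The embryo-higher share of the calls was 54.5% as deposited, 64.6% (676 against 370) with median-of-ratios, 68.4% (786 against 363) with upper-quartile scaling, 65.9% (1010 against 523) with libraries rescaled without the rDNA-related reads, 73.6% (1043 against 375) without the 20 highest genes of each tissue and with sums made equal, and 48.4% (999 against 1065) with TPM, at its looser cutoff. These settings shifted the median by 0.31, 0.39, 0.28, 0.51 and −0.22. The balance was also on the side of ovary with a pseudocount of 5 (271 against 304), a 2-fold threshold (1434 against 2533) and subtraction of the intestinal share (578 against 899).

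Embryonic patterning transcription factors stood above all random lists in the embryo, with 23 of 123 higher there, 4 in ovary and 96 in neither (median 0.50). The homeobox gene pal-1 (PgR134_g022), a caudal-type regulator of posterior fates, was at 38.1 RPKM in embryo and 0 in ovary, while the homeobox genes ceh-20 (PgB10_g071) and irx-1 (PgR023_g122) had 102 and 88.2 in embryo and 71.6 and 106 in ovary. Histones had a median of 0.25 (percentile 99.98), with 1 of 34 called, and histone H3 (PgR012_g077) was at 9260 RPKM in embryo and 3961 in ovary. Splicing genes were also above random lists (median 0.17, or −0.06 with TPM; 1 of 105 higher in embryo, 2 in ovary), as were the sperm list (median 0.26, percentile 99.44; 7 of 75 against 0) and the kinases (median 0.00, percentile 97.7; 19 of 568 against 18). The sperm list lay within the range of random lists with median-of-ratios (percentile 96.5) and upper-quartile scaling (96.1), and the kinases with a pseudocount of 0.1 (97.09). Of the sperm list, PgE404_g001 and PgE404_g002 had 24.4 and 17.4 RPKM in embryo, each 13.5% of its intestinal value. Whether signal shared between tissues raised this list was not tested. Yolk proteins were higher in embryo for 3 of 4 members (median 5.34). These were PgR126X_g018, PgR126X_g019 and PgR126X_g020, with 96.4, 51.4 and 62.5 RPKM in embryo and 961, 501 and 628 in intestine, so that the embryo values were 10.03%, 10.26% and 9.952% of the intestinal ones, near the share of the intestinal genes described above. As they overlap, their agreement is not that of 3 separate genes. Ribosomal proteins (median −1.18; 1 of 193 higher in embryo, 8 in ovary), mitochondrial respiration (−1.11; 1 of 80 against 5) and small RNA genes (−1.13; 0 of 24 called) lay below random lists, with 40S ribosomal protein S15 (PgR062_g016) at 227 RPKM in embryo and 724 in ovary. Mitosis genes were lower as well (−0.49, percentile 1.97; 1 of 89 against 13), a position lost with a pseudocount of 0.1 (percentile 2.93) and with values summed per gene (3.74).

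A gene was called enriched in a tissue when it stood at least 4-fold above each of the other 4 tissues with at least 5 RPKM. By this rule 1425 genes were enriched in testis, 271 in ovary, 286 in embryo, 293 in intestine and 551 in carcass. The intestinal count would be lowered by a share of intestinal signal in the carcass, which was not subtracted. The highest testis-enriched genes included MFP1-beta PgR166_g003 at 2738 RPKM, in whose span PgR166_g004 lies, next to PgE404_g001, PgE050_g003 and the MSP-domain genes named above. Among ovary-enriched genes, the small heat shock protein ov25-1 (PgR016_g064) followed chondroitin proteoglycan 3, PgB05_g043 and the immunosuppressive ovarian message protein with 3965 RPKM in ovary and at most 263 elsewhere. Of the embryo-enriched genes that follow, PgR046_g002 (53241 to 68774) and PgR046_g003 (54050 to 69877) overlap on opposite strands, so they may hold reads of 1 locus. The highest embryo-enriched genes were regulator of rDNA transcription protein 15, TAR1 (PgR046_g003; 25985 RPKM), a gene annotated as ATP-dependent RNA helicase A (PgR039_g031; 5418), the fatty acid-binding protein PgR015_g036 and a Pol polyprotein of the R2 retrotransposable element (PgR016_g098; 2142), so that 3 of these 5 are rDNA-related by annotation. In intestine they were C-type lectin protein 160, the disaccharide-digesting enzymes maltase-glucoamylase (PgR007_g177; 3508 RPKM) and sucrase-isomaltase (PgR007_g176; 3376), of which the first lies inside the span of the second on the opposite strand, a zonadhesin (PgR030_g100; 2355) and aminopeptidase N (PgR003_g017; 2322). In carcass they were actin-2 (PgR195X_g002; 21620 RPKM), OV39 antigen (PgB20_g007; 15184) and cuticle collagens. Of the fixed lists, testis-enriched genes held 55 of 75 sperm genes and 192 of 568 kinases, and carcass-enriched genes 40 of 211 collagens and cuticlins, 30 of 85 muscle genes and 17 of 91 immunity genes. Vitellogenin genes split, with 3 of 4 enriched in intestine, of which PgR126X_g018 was highest at 961 RPKM, and PgR057_g055 enriched in testis at 54.4 RPKM.

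**Figure D2:**
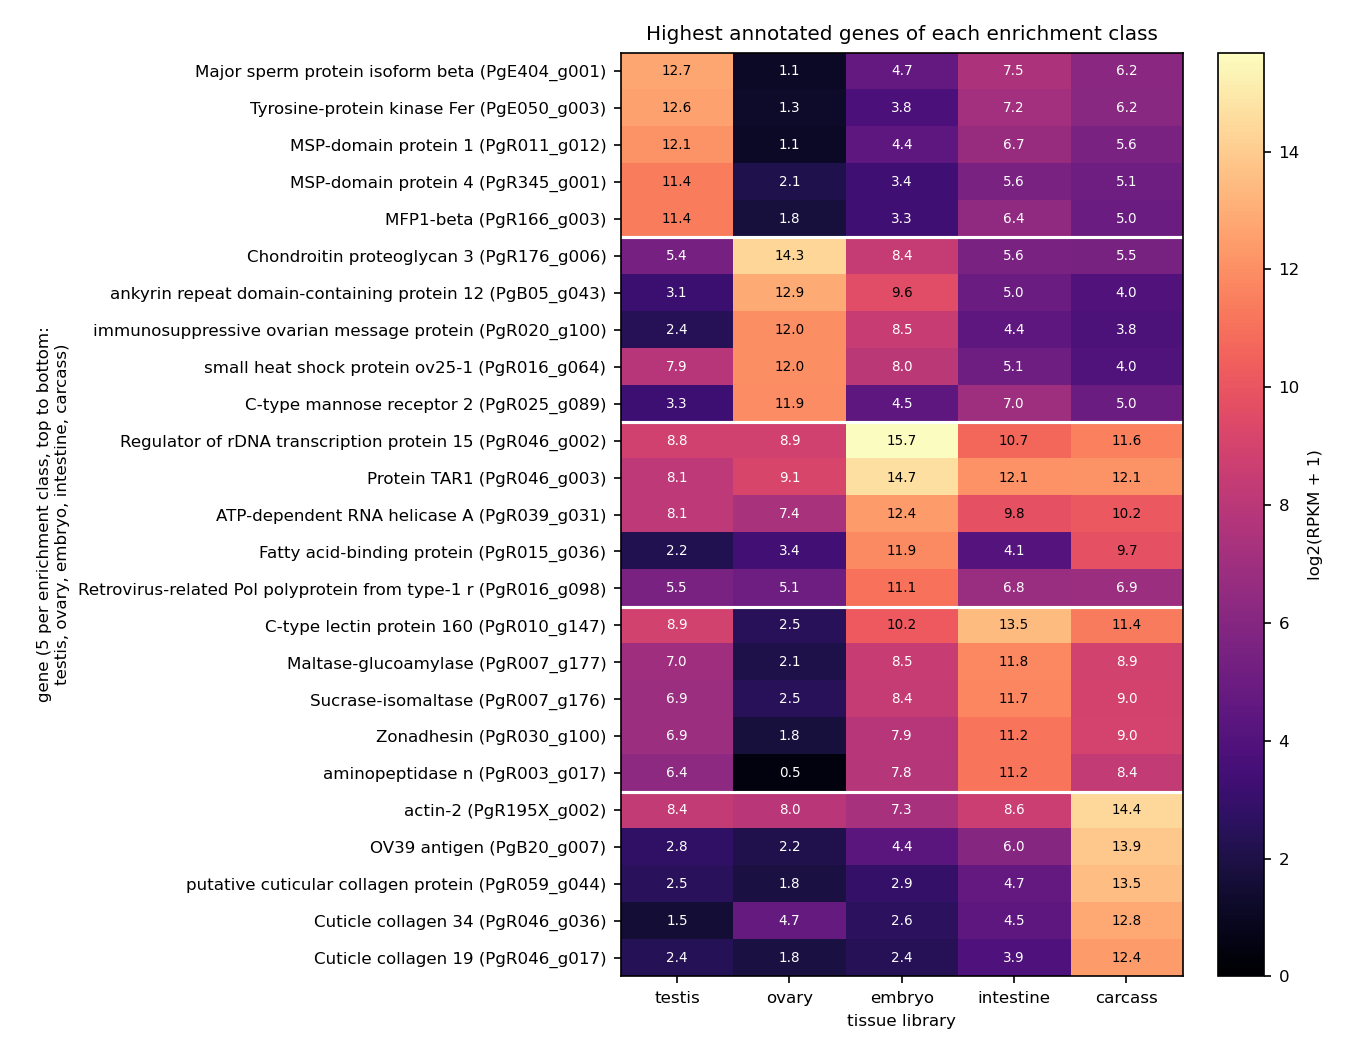
Values of the leading tissue-enriched genes, 5 for each tissue, as log2(RPKM + 1) in the 5 tissues, 1 library each and no error bars. Each group of genes is highest in its own tissue, such as chondroitin proteoglycan 3 at 20766 RPKM in ovary and actin-2 at 21620 RPKM in carcass.

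A few lists lay within the range of random lists in all 4 comparisons, although meiosis genes and digestive peptidases left it under some alternatives. Oocyte and eggshell genes had 6 members, of which 1 was higher in testis and 2 in ovary, and this list held a methyl-CpG-binding protein and missed the genes annotated as chondroitin proteoglycan. Its highest member, an eliminated chitin synthase (PgE051_g001), an enzyme that makes chitin, was at 419 RPKM in ovary, 206 in embryo, 13.7 in testis and at most 4.7 in intestine and carcass. Meiosis genes had 1 of 18 higher in testis and 1 in ovary. Transposons and repeats had 6 of 71 higher in testis and 4 in ovary, and 6 higher in embryo than in ovary. Their most abundant member, a Pol polyprotein of the R2 retrotransposable element (PgR139_g003) and so 1 of the 25 rDNA-related genes, had 85011 RPKM in embryo and between 5026 and 26256 in the other tissues. Of 47 ciliated sensory neuron genes, 6 were higher in testis and 2 in ovary, and cytoplasmic dynein 2 heavy chain 1 (PgR017X_g084) was at 52.1 and 91.4 RPKM in these tissues. Digestive peptidases, described above, also had 27 of 260 members higher in testis and 36 in ovary.

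**Figure D3:**
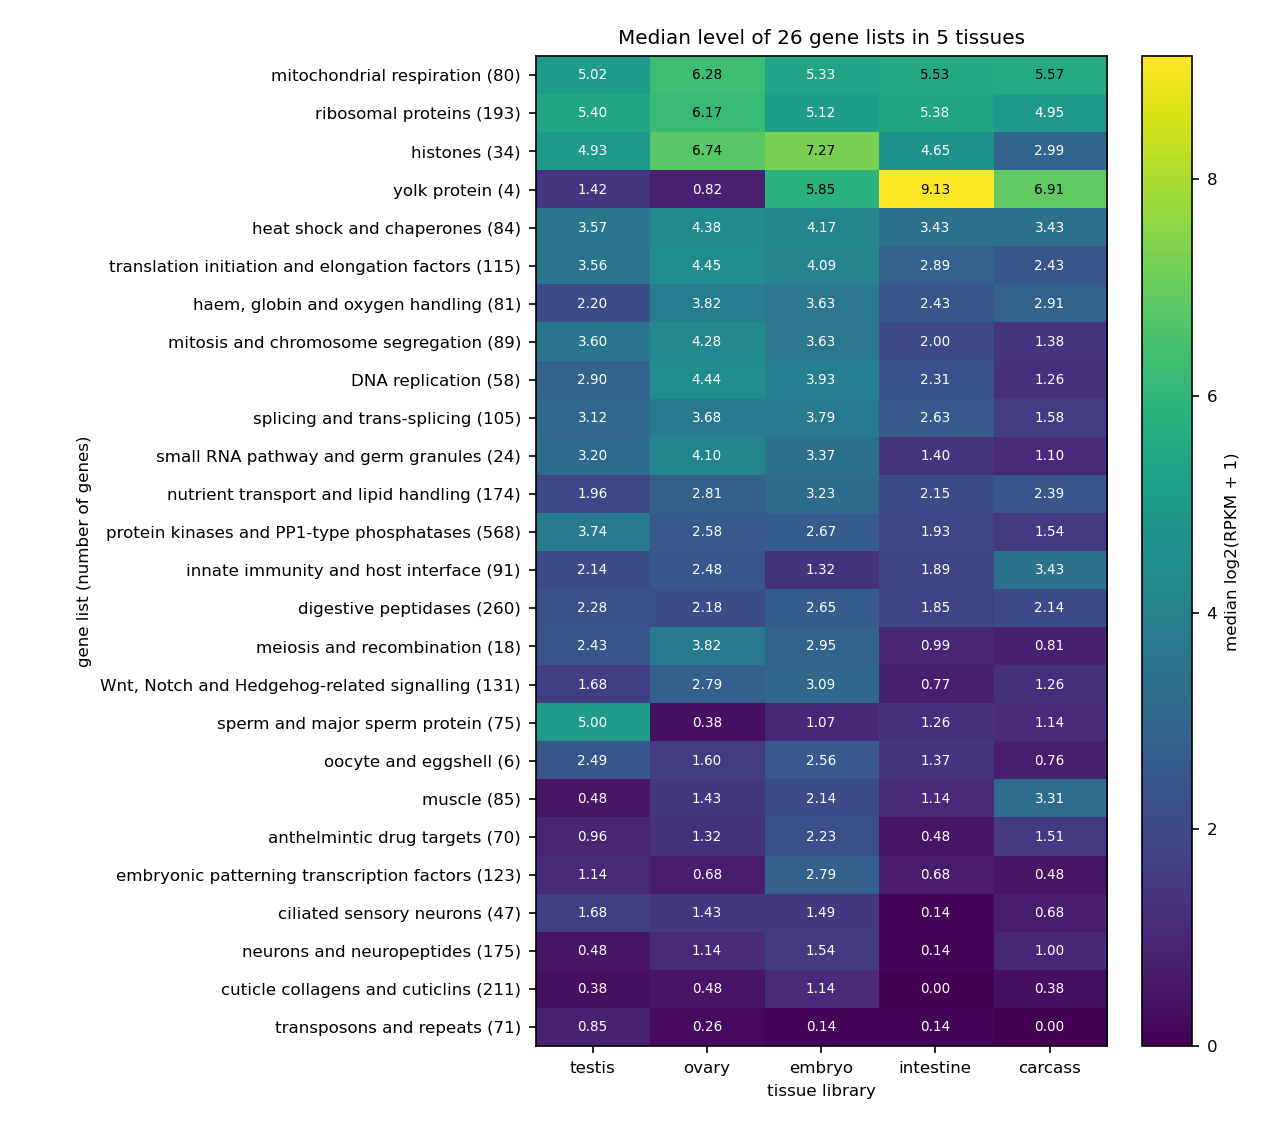
Median log2(RPKM + 1) of the members of each fixed gene list in the 5 tissues, 1 library each; the medians carry no error bars. The sperm list has its highest median in testis (5.0, against 0.38 in ovary) and the muscle list in carcass (3.31, against 1.14 in intestine).

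The mark for eliminated DNA separated 985 genes from 14042 retained ones, and the comparison asked where genes lost from somatic cells are expressed. Eliminated genes were frequently testis genes: 411 of the 985 (41.7%, exact interval 38.6% to 44.9%) were testis-enriched, against 7.22% of retained genes (odds ratio 9.20, interval 7.96 to 10.6; two-sided Fisher's exact test across genes, adjusted p = 7.9e-176 over 5 tissues). They included PgE404_g001 and PgE050_g003 at 6856 and 6163 RPKM, a gene annotated as splicing factor arginine/serine-rich 7 (PgE082_g001) at 1322, a pyruvate dehydrogenase E1 alpha subunit (PgE097_g003) at 900.1 and a branched-chain aminotransferase (PgB36X_g004) at 487. By the same exact test, eliminated genes were few among intestine-enriched genes (1 gene, odds ratio 0.0479, adjusted p = 1.2e-07) and carcass-enriched genes (3 genes, odds ratio 0.0752, adjusted p = 1.4e-12). The first of these calls was lost with an 8-fold threshold (odds ratio 0, interval 0 to 4.30, exact adjusted p = 1) and the second with 1 gene per annotation text among eliminated and among retained genes (odds ratio 0.333, exact adjusted p = 0.061). Genes absent from somatic DNA would be low in intestine and carcass, so both deficits are largely given by the mark itself. The rule for testis enrichment asks for 4-fold above both of these tissues, so part of its odds ratio is built in. The rule for ovary asks the same. The intestinal gene was PgE495_g001, annotated hypothetical, with 61.9 RPKM. The carcass genes were an ASABF-alpha (PgE286_g001; 235 RPKM), a cre-grl-4 (PgE754_g001; 22.7) and a cuticular collagen (PgE085_g002; 13.6). Eliminated genes that the comparisons above do not name were picked for this account after their values were seen. The exact test did not pass for ovary (17 genes, odds ratio 0.953, interval 0.544 to 1.565, adjusted p = 1) or embryo (11 genes, odds ratio 0.565, interval 0.278 to 1.03, adjusted p = 0.0863). Eliminated genes were fewer by this exact test with a 2-fold threshold in both (adjusted p = 0.0043 and 0.0015), and in embryo also with a pseudocount of 0.1 (exact adjusted p = 0.040) and with TPM (exact adjusted p = 0.023). The odds ratios of the tissues were not tested against each other. The ovary-enriched ones were led by tubulin alpha-2 (PgE040_g001; 860.3 RPKM), the phosphatase PTPN9 (PgE029_g001; 369) and a succinyl-CoA:3-ketoacid transferase (PgE133_g001; 325), and the embryo-enriched ones by an SCF ligase subunit (PgE042_g007; 33.8) and DAZ protein 1 (PgE195_g002; 31).

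**Figure D4:**
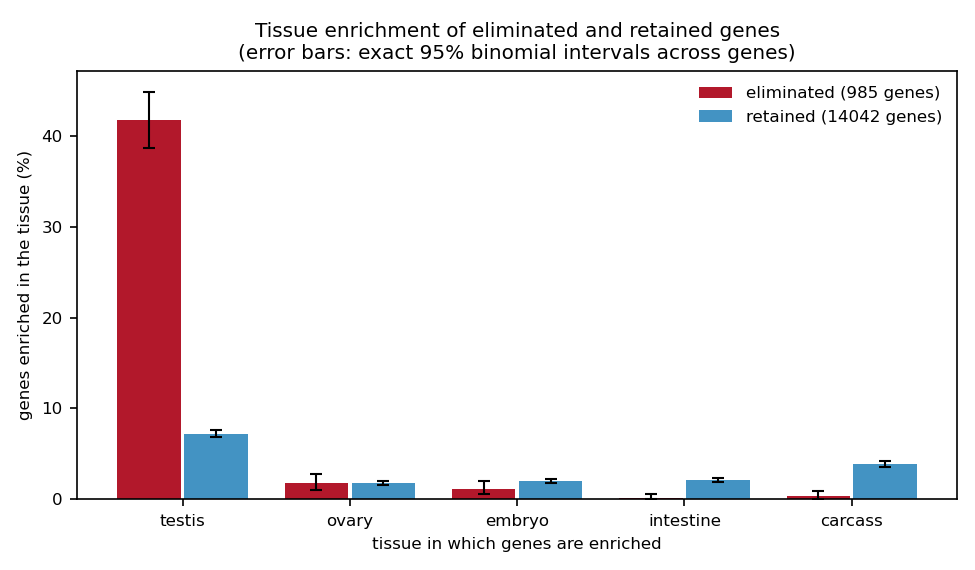
Percentage of the 985 eliminated and of the 14042 retained genes that are enriched in each tissue; bars start at 0 and error bars are exact 95% binomial intervals across genes. Testis enrichment covers 41.7% of eliminated and 7.22% of retained genes, while intestine and carcass enrichment cover 0.102% and 0.305% of eliminated genes.

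Eliminated genes had a median of 13.6 RPKM in testis, 1.0 in ovary, 2.0 in embryo, 0.4 in intestine and 0.2 in carcass, and retained genes 4.1, 7.7, 7.0, 3.0 and 2.5. Of the eliminated genes, 173 (17.6%) were among those higher in both germline tissues than in both somatic ones, against 2.36% of retained genes (odds ratio 8.80, two-sided Fisher's exact p = 1.3e-80), and 0 were among the 255 higher in soma (p = 5.3e-08; upper bound of the odds ratio 0.204). Loss of these genes from somatic cells would by itself push both differences this way. Eliminated genes lay on all 466 scaffolds with names in PgE, which held 883 genes, and 102 lay among the 2506 genes of the PgB scaffolds. The PgR scaffolds held 0. Of the 593 eliminated genes with an informative annotation, 470 (79.3%) shared its text with a retained gene. Serine/threonine-protein kinase was carried by 10 eliminated and 22 retained genes, tubulin alpha chain by 10 and 6, tau-tubulin kinase 2 by 8 and 11, and tudor domain protein by 7 and 10. Other annotations were found on eliminated genes alone. The sperm vesicle fusion protein fer-1 was on 6 genes, of which 5 were testis-enriched, eukaryotic initiation factor 4E-3 on 4 and U2 small nuclear ribonucleoprotein B on 5, all of them testis-enriched. Argonaute ALG-6 and DAZ protein 1 were on 5 genes each. Across the 26 fixed lists, eliminated genes were in excess among transposons (22 of 71, odds ratio 6.52, adjusted p = 1.1e-08), kinases (77 of 568, 2.34, 1.5e-08), translation factors (21 of 115, 3.23, 1.4e-04), mitosis (17 of 89, 3.41, 3.7e-04), sperm genes (15 of 75, 3.60, 4.6e-04) and small RNA genes (7 of 24, 5.90, 0.0021), by two-sided Fisher's exact tests. They were few among neuronal genes (1 of 175, odds ratio 0.0810, adjusted p = 7.0e-04), digestive peptidases (4 of 260, 0.220, 7.6e-04), haem handling (0 of 81, 0.018), mitochondrial respiration (0 of 80, 0.025), collagens (5 of 211, 0.343, 0.025) and Wnt, Notch and Hedgehog-related genes (2 of 131, 0.219, 0.027) by the same exact tests.

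The 5′ marks told which genes have a transcript found in the spliced leader library, made by PCR from the short exon that nematodes join to many messages, and which in the TeloPrime library, made by PCR from capped 5′ ends. Both came from mixed samples, and this comparison was chosen after the table was seen. The submitters head the first mark trans-splicing and the second non-trans-spliced, so the shares of the marks are not separate findings. Of all 15027 genes, 982 carried both. Testis-enriched genes carried the spliced leader mark in 16.2% of cases, against 53.5% in ovary-enriched, 22.4% in embryo-enriched, 53.9% in intestine-enriched, 42.3% in carcass-enriched and 36.1% of all genes. The TeloPrime mark was carried by 44.1% of testis-enriched genes, 28.4% of ovary-enriched, 3.85% of embryo-enriched, 28.0% of intestine-enriched, 37.4% of carcass-enriched and 15.9% of all genes. PgE404_g001, PgE050_g003 and chondroitin proteoglycan 3 (PgR176_g006) had the TeloPrime mark alone, transthyretin-like protein 16 (PgR080_g022) the spliced leader mark alone, and the fatty acid-binding protein PgR015_g036 both. For testis-enriched against all other genes the odds ratio was 0.313 for the spliced leader (interval 0.270 to 0.363; two-sided Fisher's exact test across genes, adjusted p = 9.1e-67 over 10 tests) and 5.29 for TeloPrime (4.71 to 5.95, adjusted p = 2.4e-158). Abundance affects both marks, and the odds ratios among genes whose highest value was 100 to 1000 RPKM were 0.181 and 2.54. Eliminated genes carried the spliced leader mark less often than retained ones (14.3% against 37.6%, odds ratio 0.277, exact adjusted p = 2.5e-55), and so did eliminated genes among the testis-enriched (odds ratio 0.638, exact adjusted p = 0.0097). For TeloPrime the sides differed: the odds ratio of eliminated genes was 1.25 over all genes (exact adjusted p = 0.010) and 0.502 among testis-enriched genes (exact adjusted p = 1.8e-08). The excess over all genes was not tested at like abundance, where the TeloPrime mark was on 52.3% of eliminated and 54.6% of retained genes at 100 to 1000 RPKM, and on 21.4% and 18.1% at 20 to 100 RPKM.

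**Figure D5:**
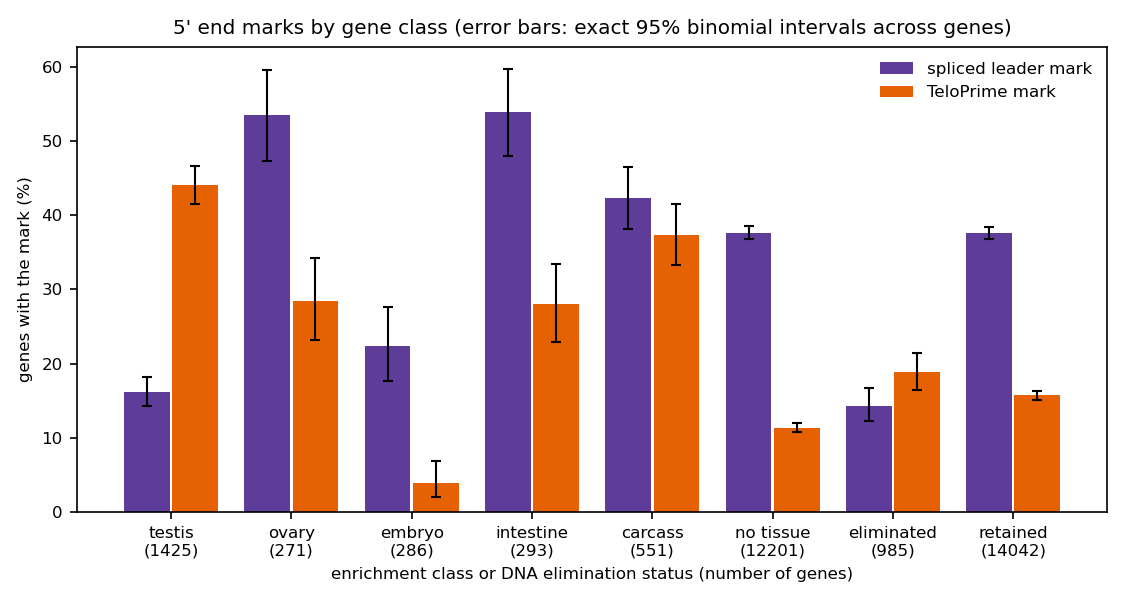
Percentage of genes with the spliced leader mark and with the TeloPrime mark, by tissue of enrichment and by elimination; bars start at 0 and error bars are exact 95% binomial intervals across genes. Testis-enriched genes have 16.2% with the spliced leader mark and 44.1% with the TeloPrime mark, and eliminated genes 14.3% and 18.9%.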

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

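The alternatives that subtract signal shared between tissues, keep 1 gene per annotation, rescale the libraries without rDNA-related reads, leave out genes inside a gene on the opposite strand, or use the authors' choice of transcript, and TPM for the eliminated genes and lists, were added after the results were seen. The others were planned. No paired analysis was possible because each tissue has 1 library. Scaling by TMM was not run, since the values are not counts. Of 226 counts under an alternative, 171 stayed within 1.5 times of the reported one and 55 did not; of 624 list medians, taken relative to random lists, 563 stayed within their bootstrap interval and 61 moved, with 0 reversed; of 1236 values of named genes, 870 stayed within counting error, 361 moved and 5 reversed; of 20 correlations, 1 stayed within the sampling interval of the reported one and 19 moved; of 15 counts of detected genes, 12 stayed and 3 moved; and of 77 tests of eliminated genes, 71 kept their side of the threshold, 4 passed it and 2 no longer did. Part of the 226 counts could not move. A filter of at least 1 RPKM in some tissue leaves every call in place, since calls need at least 5 RPKM. Each subtraction of shared signal leaves comparisons without the changed tissue as they were. The number that stayed therefore overstates how stable the counts are. Where no construction is named, the cause was not tested.

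A pseudocount of 5, which shrinks the differences of low genes, left 1132 genes higher in ovary than testis (1292 in testis), 248 higher in intestine and 605 in carcass, 271 higher in embryo and 304 in ovary, 139 in germline and 102 in soma; enriched genes numbered 147 in ovary, 112 in embryo, 168 in intestine and 362 in carcass. A 2-fold threshold, looser by construction, gave 5211 genes higher in ovary than testis (2108 in testis), 2835 in intestine than carcass (1370 in carcass), 1434 in embryo than ovary and 2533 the other way, 1128 in germline and 507 in soma, and 1506 ovary-, 657 embryo- and 697 intestine-enriched genes. An 8-fold threshold gave 892, 42, 425, 250, 171 and 64 for the same comparisons, with 1454 genes higher in testis and 766 in carcass, and 87, 152 and 14 for the same tissues. Median-of-ratios scaling gave 839 genes higher in ovary than testis, 222 in intestine than carcass, 370 in ovary than embryo, 308 in germline and 528 in soma, and 106 ovary-, 111 intestine- and 892 carcass-enriched genes; upper-quartile scaling gave 1119, 256, 363, 311 and 509, and 115, 126 and 831. With TPM, whose larger values loosen the cutoff, 1757 genes were higher in intestine than carcass and 1065 in ovary than embryo, and 475 were intestine-enriched. Without the 20 highest genes of each tissue, and with sums made equal, these numbers were 1168 and 375, and 145 genes were ovary-enriched. A tau of at least 0.85 in place of the 4-fold rule gave 787 testis-, 76 ovary-, 18 intestine- and 306 carcass-enriched genes. At least 5 RPKM was listed for 7181 genes in testis, 5839 in intestine and 4987 in carcass.

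The correlation of ovary and embryo was 0.759 with a pseudocount of 0.1 and 0.769 among genes with at least 1 RPKM in some tissue, and this pair stayed the most similar and testis and carcass the least in both (0.422 and 0.321). The excess of eliminated genes among testis-enriched ones passed the exact test under every alternative run for that result. For ovary-enriched genes the odds ratio became 0.704 with a 2-fold threshold (exact adjusted p = 0.0043), and for embryo-enriched genes it was 0.529 with a 2-fold threshold (p = 0.0015), 0.556 with a pseudocount of 0.1 (p = 0.040) and 0.476 with TPM (p = 0.023), all past the threshold that the reported value missed. The deficit among intestine-enriched genes was lost with an 8-fold threshold, which left 14 such genes (odds ratio 0, exact adjusted p = 1). That among carcass-enriched genes was lost with 1 gene per annotation within each of the eliminated and retained genes, which left 331 eliminated and 6212 retained genes (odds ratio 0.333, exact adjusted p = 0.061). Without the genes that lie inside a gene on the opposite strand the odds ratios were 9.19 for testis-, 0.973 for ovary-, 0.576 for embryo-, 0.0516 for intestine- and 0.0826 for carcass-enriched genes.

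Subtraction of the intestinal share from the embryo reversed the embryo against ovary difference of C-type lectin protein 160 (−2.49), aminopeptidase N (−0.49), the proton myo-inositol cotransporter (−0.38), maltase-glucoamylase (−2.07) and ifa-1 (−0.77), by construction. It left 578 of the 801 genes higher in embryo and added none, gave 899 genes higher in ovary, and left 285 of the embryo-enriched genes. Of 104 list medians, 42 lay outside the range of random lists; 3 of these no longer did with median-of-ratios scaling, 1 with upper-quartile scaling, 0 with TPM, 3 with a pseudocount of 0.1, 1 with values summed per gene and 0 among members with at least 1 RPKM in some tissue. Another 9, 6, 4, 7, 2 and 4 medians lay newly outside that range under the same settings, in this order. Depth limits what can be said of low values most in the embryo, where 3 reads on a transcript of median length are 0.190 RPKM.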

Other observations

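All tests of explanations in this part were chosen after the result they address was seen.

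Of the 85 genes of the muscle list, 30 were enriched in carcass, 2 in testis, 1 in embryo, 1 in intestine and 0 in ovary, and of the 175 neuronal genes 5 in carcass, 5 in testis, 4 in embryo, 3 in intestine and 1 in ovary. Some of the most abundant members of these lists were highest in ovary. Myosin-4 (PgR016_g050) stood at 498 RPKM in ovary and 398 in embryo, against 5.7 in testis, 2.5 in intestine and 2.3 in carcass. FMRFamide-like peptide 8 (PgR013_g104), a neuropeptide precursor, had 172 RPKM in ovary, 61 in embryo and at most 1.8 in the other tissues, and synaptotagmin-1 (PgR236_g001), a calcium sensor of vesicle release, 196 in ovary, 91.4 in embryo, 50.6 in intestine, 8.4 in carcass and 1.2 in testis. Syntaxin-18 (PgB05_g029) was instead at 269 RPKM in testis and at most 5.4 elsewhere. A metalloproteinase inhibitor (PgR122_g019) had 2305 RPKM in ovary, 509 in embryo and 36.8 in testis.

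Among targets and carriers of anthelmintic drugs, tubulin beta-2 (PgR007_g022) was abundant in all 5 tissues, from 458 RPKM in intestine to 1534 in embryo. Tubulin beta-1 (PgE153_g002), which is marked as eliminated, had 256 RPKM in ovary, 331 in embryo and 82.1 in testis, against 8.2 in intestine and 1.7 in carcass. The efflux pump pgp-1 (PgB04_g139) stood at 321 RPKM in intestine and 56.2 in carcass, and multidrug resistance-associated protein 1 (PgR121_g016) at 10.2 and 112. Glutathione S-transferase 2 (PgB04_g156), a detoxifying enzyme, had 4058 RPKM in intestine, 2304 in carcass, 999 in ovary, 664 in testis and 437 in embryo.

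Genes abundant in intestine and low in ovary kept nearly one ratio in the embryo: of the 102 such genes, 0% lay below 0.5 times the median share of 10.3% (exact upper bound 3.55%), as a fixed share of intestine-derived RNA or reads in the embryo library would give. Expression of these genes by the embryo itself would need nearly the same ratio to intestine in all of them, since 95.1% (88.9% to 98.4%) lay within 1.5 times of the median. Over the same genes this was 73.5% for carcass and 60.8% for testis, which may hold intestinal signal themselves. The near-constant ratio was seen before these tests were chosen, so they restate it and cannot decide between the explanations. Without genes that lie inside a gene on the opposite strand, 91 remained, with a median of 10.4% and 94.5% within 1.5 times of it. The 102 genes include the testis-enriched PgE404_g001, PgE404_g002 and PgE050_g003. Among 140 genes of 20 to 100 RPKM in intestine the embryo share was a median 11.4%, 65.7% lay within 1.5 times of it and 6.43% below 0.5 times of it. For these genes 60.7% lay within 1.5 times of the median for carcass and 49.3% for testis. At this level the embryo ratio was little more uniform than that of carcass and does not argue against expression by the embryo. Carried-over tissue, mixed reads between libraries and real embryonic expression of a part of the genes stay open, and no biological explanation from the design was tested.

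Eliminated genes were not all at 0 in intestine and carcass, both labelled somatic. For testis-enriched genes with at least 100 RPKM, the intestinal value was a median 1.96% of the testis value for 118 eliminated and 1.85% for 328 retained genes (ratio 1.06, interval 0.893 to 1.20), and in carcass 1.07% and 1.19% (ratio 0.895, 0.830 to 0.971), so a small share of testis-derived RNA or reads may account for these. It may also account for PgE404_g001, PgE050_g003 and PgE404_g002, at 180, 142 and 129 RPKM in intestine and 74, 70.3 and 47.1 in carcass. It does not account for the other 21 (87.5%) of the 24 eliminated genes with at least 20 RPKM in both tissues, which stood above 5 times that share in both. For a part of these 21, reads of one repeated sequence counted at several genes are a candidate explanation: 12 of them matched the profile of the highest one, annotated dhx8 (PgE060_g001; 7303, 3596, 3595, 2106 and 3126 RPKM in testis, ovary, embryo, intestine and carcass), within 1.5 times in all tissues. That was 12 of the other 23 eliminated genes at this level against 4 of 1159 retained genes (odds ratio 299, interval 76.6 to 1477). The profile was taken from 1 of these same eliminated genes after they were seen. The interval treats as separate genes that may hold the same reads. The odds ratio therefore describes the likeness and cannot test the explanation. Retained copies elsewhere in the genome stay open as the origin of those reads, and expression from DNA that was not eliminated was not tested.

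Scaffolds whose names end in X held 2862 genes on 84 scaffolds, and 44 (1.54%) of these were testis-enriched, against 11.4% of genes elsewhere (odds ratio 0.122, interval 0.0879 to 0.165; two-sided Fisher's exact p = 4.3e-80). The deficit was not explained by eliminated genes, few of which lie there (odds ratio 0.138 among retained genes, 0.0960 to 0.192), or by genes of low value (0.125 among genes with at least 5 RPKM in some tissue). Among genes with an informative annotation, families of testis genes with many copies did not explain it either (0.145 with 1 gene per annotation, 0.0714 to 0.265). Of the 1425 testis-enriched genes 778 have such an annotation, and families among the others were not examined. For the other 4 tissues the odds ratios lay between 0.812 and 1.11, with exact adjusted p-values from 0.559 to 0.956, and the median log2(RPKM + 1) on X-named scaffolds was 1.93 in testis and 3.39 in ovary, against 2.59 and 2.87 elsewhere. If the X stands for a sex chromosome, which the sources used here do not say, a low share of testis genes there may be a property of that chromosome; no biological explanation was tested.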
